A study of Homo sapiens with 2 samples.

How the data were processed

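RNA was sequenced from U2OS cells, a human osteosarcoma line, that carried a FLAG-tagged copy of the repair protein FANCD2. Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries with a stranded kit and sequenced from both ends. There were 2 libraries, 1 from cells given the solvent DMSO and 1 from cells given 0.4 µM aphidicolin (APH), each after 24 h. The deposited table gives raw counts of reads per gene, not normalized, in 1 column for each library. Per the submitters' processing notes, the reads were handled with bcl2fastq 1.8.4, TopHat2, SAMtools and HTSeq on the hg19 build. The annotation release, the strand setting of the counting, any filter and the other versions are not given in the sources used here. Ribosomal RNA depletion keeps RNA without poly(A) tails, so histone and small structured RNAs were counted along with other transcripts. Reads from a gene and a gene that overlaps it cannot be told apart without the strand setting, and near-identical copies may share or lose reads.

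The table names its columns control and case. The control column was taken as the DMSO library because the label calls that sample the solvent control. The case column was taken as the APH library because it is set against the control and APH is the only other sample. Every direction in the text rests on that reading.

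The table lists 57773 genes with hg19 coordinates. For 14 of them 1 of the 2 counts was missing, 3 in the DMSO library and 11 in the APH library, and these genes were left out of totals and comparisons. The remaining 57759 genes summed to 17837043 counts in the DMSO library and 18641741 in the APH library. Chromosome names were missing for 2924 genes, so no chromosome is printed for them. Gene type, longest transcript and GC content came from GENCODE release 29, matched by gene identifier for 52338 genes and by symbol as well for 54384 in all. That annotation is on another build, and none of its coordinates were used. Of the 12522 genes compared, 12433 (99.3%) had a GC content.

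Both libraries were put on 1 scale with TMM factors from edgeR 4.0.16. The log2 ratio of a gene is that of its APH count over its DMSO count, each with 0.5 added, less the log2 of the scale (0.162). Positive values mean a higher level in the APH library. Each ratio has an exact Clopper-Pearson 95% interval, which covers counting error only, because reads without molecular identifiers are not independent molecules and cultures were not repeated. With 1 library per condition, no p-value was computed, and statements compare these libraries. A gene was counted as higher or lower when its summed count was at least 100, its ratio at least 1.5-fold and its interval excluded equality. A count of 0 was set against a floor of 3 counts in that library, which gives a bound in place of a ratio.

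For each of 29 gene lists, fixed before the data were examined, the median log2 ratio of members with a summed count of at least 100 was taken. Its interval came from order statistics. Its place was found among 10000 random lists of the same size matched on mean level in 20 bins. Genes of at least 300 kb were compared with genes under 30 kb by the difference of medians, with 2000 bootstrap draws and 10000 matched random sets. Named genes followed a rule fixed at the same time. It took FANCD2, the 10 highest and 10 lowest ratios among higher and lower genes whose type or symbol marks them as protein-coding or long non-coding, and the 5 most counted fragile-site genes. It also took the highest, lowest and most counted member of each list, and the 5 highest and 5 lowest ratios among genes with a summed count of at least 2000. Some genes the rule took, and 1 test that needed such a gene, are not reported here. Other members are named as examples of their list, after their values were seen. A further 6 lists were written after the data were examined and are used in the closing section, apart from counts of liver and breast markers beside the genes they bear on.

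The scripts were tested on simulated counts for 12520 genes drawn from the libraries' own levels, with Poisson error alone. All 50 genes raised 2-fold, 48 lowered 2-fold, 50 raised 3-fold and 49 lowered 3-fold were called, along with 31 of 12323 unchanged genes (0.252%). Of 300 unchanged lists, 25 lay beyond the 2.5 and 97.5 percentiles. That is more than those limits imply, so a place near them should be read with caution. All 300 lists shifted upward by 0.25 were recovered, and smaller shifts were not simulated. Alternatives were scaling by total counts, by upper quartiles and by DESeq2 1.42.0 median ratios, other count minimums, a 2-fold threshold, a prior count of 5, no interval, protein-coding genes alone, other span limits and random lists matched on span. Calculations used R 4.3.3, Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.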

Results

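The transcriptomes of U2OS osteosarcoma cells that carry FLAG-tagged FANCD2 were compared after 24 h with solvent (DMSO) or with 0.4 µM aphidicolin (APH). Aphidicolin inhibits the replicative DNA polymerases, and a low dose slows replication forks and exposes common fragile sites. The comparison asked how transcript levels differ under this mild replication stress. The DMSO library held 17837043 counts and the APH library 18641741, over 57759 genes. Each condition had 1 library, so no difference reported here has a replicate check. Intervals of single genes and of summed ratios are 95% counting intervals. Those of medians and of the difference between long and short genes reflect the spread among genes.

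KISS1, the gene of the kisspeptin peptides, stood far higher in the APH library, with 1182 counts against 296 (log2 ratio 1.83, interval 1.65 to 2.02). Replication-dependent histone genes stood lower, with HIST1H1A, a linker histone gene, at 1008 counts against 2608 (log2 ratio -1.53, interval -1.64 to -1.43). ALB, the gene of serum albumin, had 1819 counts in the DMSO library and 0 in the APH library, at least 678-fold lower against a floor of 3 counts. Reads from liver RNA in the DMSO library may account for the ALB counts, as the closing section describes. FANCD2 itself, the tagged gene (ENSG00000144554, hg19 chromosome 3, 10068098 to 10143614), had 1445 counts against 1342 and a log2 ratio of -0.06 (interval -0.16 to 0.05). Such extremes were few, and 95.1% of the 12522 genes compared lay within 1.5-fold.

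In all, 410 genes were at least 1.5-fold higher in the APH library and 198 were lower. The lower genes included 31 replication-dependent histone genes, 7 small structured RNAs and 10 genes of a liver marker list written after the ratios were seen, and 150 were counted without these 3 lists. The higher genes made up 67.4% of those counted, against 84.5% when the libraries were scaled by total counts and 54.5% with upper quartiles. At a 2-fold threshold, 68 genes were higher and 46 lower.

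The 10 largest ratios upward spanned several kinds of gene. SPDEF, which encodes an epithelial transcription factor, had the highest at 1.85 (interval 1.15 to 2.66) from 82 counts against 20. It is also on a list of breast tissue markers, and reads from breast tissue RNA were left undecided (closing section). KRT75, a hair follicle keratin gene, reached 1.65 (1.14 to 2.21), and MYH15, a myosin heavy chain gene, 1.54 (1.19 to 1.92). MEGF10, the gene of a receptor for engulfing dying cells, had 357 counts against 120 and a ratio of 1.41 (1.11 to 1.72). OAS1, an interferon-induced sensor of double-stranded RNA, reached 1.37 (0.78 to 2.04), and PTGS2, which encodes the inducible cyclooxygenase, 1.36 (0.76 to 2.02). The transmembrane protein gene TMEM40 stood at 1.48 (0.83 to 2.21) and the long non-coding RNA gene RP11-416I2.1 at 1.35 (0.91 to 1.83). C6orf223 had 563 counts against 156, while RP5-1120P11.1, which overlaps it on chromosome 6 and was singled out after its values were seen, had 71 against 254. Their summed log2 ratio was 0.47 (0.29 to 0.65), and reads of the pair cannot be assigned with certainty.

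Of the 10 lowest ratios, 9 belonged to genes of plasma proteins or liver enzymes. Reads from liver RNA in the DMSO library may account for these genes, so their ratios need not reflect an effect of treatment (closing section). TF, which encodes transferrin, was at least 49.97-fold lower in the APH library (0 counts against 134), FGA, a fibrinogen chain gene, at least 44.4-fold (0 against 119), and TTR, the transthyretin gene, at least 39.5-fold (0 against 106). The alcohol dehydrogenase gene ADH1B had 2 counts against 123 (log2 ratio -5.79, interval -9.17 to -4.22) and the apolipoprotein gene APOA1 had 2 against 113 (-5.67, -9.05 to -4.10). HP, the haptoglobin gene, had 5 against 156 and APOE 13 against 104, with ratios of -4.99 (-6.77 to -3.87) and -3.11 (-4.12 to -2.33). TBX10, a T-box factor gene, had 24 counts against 140 (-2.68, -3.40 to -2.07).

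Among the 4167 genes with a summed count of at least 2000, LOX, which encodes the collagen cross-linking enzyme lysyl oxidase, had the highest ratio at 0.88 (0.77 to 1.003). SDC1, the gene of the cell-surface proteoglycan syndecan, followed at 0.75 (0.66 to 0.84). MDFI, an inhibitor of myogenic factors, and IL2RB, an interleukin receptor chain, stood at 0.69 and 0.68. The lowest were SCARNA10 at -1.68 (-1.79 to -1.57) and SNORD3A at -1.66 (-1.69 to -1.63), RNAs of the Cajal body and the nucleolus, followed by HIST1H1A, HIST1H2BL at -1.48 and HIST1H3D at -1.30. LOX overlaps SRFBP1 (log2 ratio -0.32) and SCARNA10 lies within NCAPD2 (0.01), so their counts depend on how overlapping reads were assigned.

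**Figure D1:**
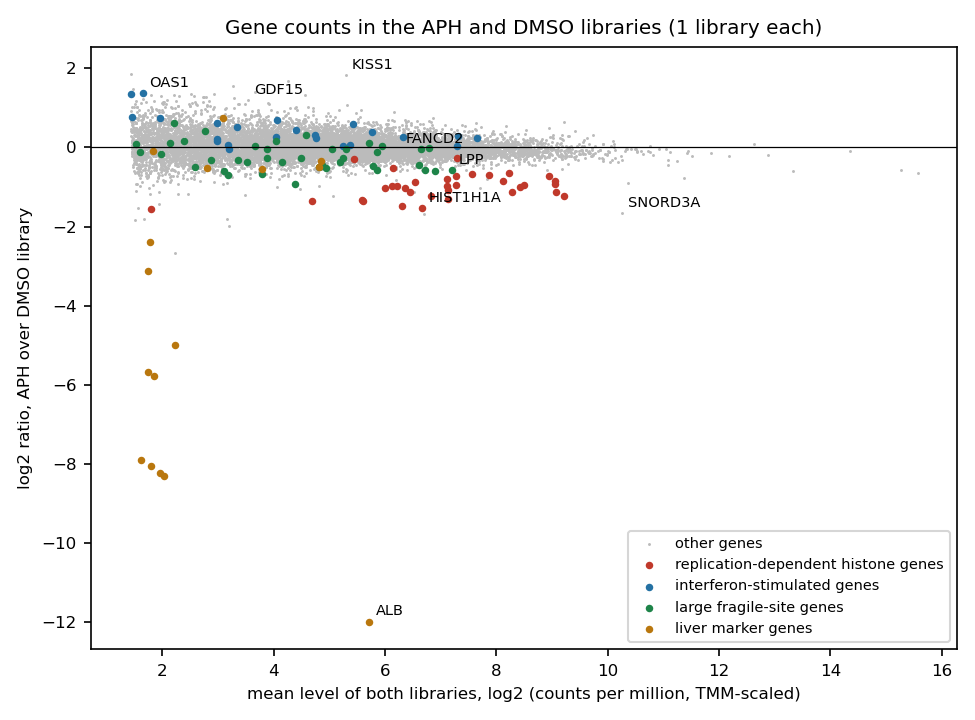
Log2 ratio of the APH over the DMSO library (vertical axis) against mean level in log2 CPM, TMM-scaled (horizontal axis), with 1 point for each of 12522 genes and 4 gene lists in colour. Histone genes lie below 0 at high levels, and genes with 0 counts are drawn with 0.5 added to each count. Of 16 liver marker genes, 10 are at least 1.5-fold lower, with ALB farthest down, 1 is higher and 5 are neither.

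Replication-dependent histone genes, whose mRNAs accumulate in S phase and mostly end in a stem-loop in place of a poly(A) tail, were lower as a class. Of 34 measured members, 31 were at least 1.5-fold lower and none was higher. The median log2 ratio was -0.98 (interval -1.13 to -0.84), lower than in all 10000 random lists matched on level. The most counted member, HIST1H1C, had 6882 counts against 14381 (-1.23, -1.27 to -1.18). HIST1H4K was lowest at -1.55 (-2.18 to -0.98) and HIST2H2AB highest at -0.27 (-0.34 to -0.19). Summed over the members, the DMSO library held 152750 counts and the APH library 89066. Histone copies are near-identical, so the split of reads among single members is uncertain.

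Small nuclear and nucleolar RNAs, which serve splicing, RNA processing and protein targeting, had a median log2 ratio of -0.60 (interval -0.97 to -0.09) over 13 measured members, lower than in all random lists. The interval included 0 with total counts (-0.50, -0.88 to 0.01) and with a count minimum of 20 (-0.53, -0.88 to 0.07). The 7 lower members included SNORD3A, SCARNA10, and RN7SL1, the RNA of the signal recognition particle, with 733673 counts against 1020074 (-0.64). RMRP, the RNA of a nuclear endoribonuclease, was highest at 0.08 (0.07 to 0.09), and RN7SK, which holds back transcription elongation, was at -0.09. RN7SL1 and RN7SL2 are near-identical copies. Structured RNAs of this kind took 14.5% of counts in the DMSO library and 11.07% in the APH library. Nuclear long non-coding RNAs had a median of -0.24 (-0.36 to -0.05) over 14 members, again lower than in all random lists, with none past 1.5-fold, and it was -0.14 (-0.26 to 0.05) with total counts. MALAT1, a nuclear speckle RNA, had 19669 counts against 22550 (-0.36, -0.39 to -0.33), while SNHG12 stood at -0.40 and HOTAIR at 0.26 (-0.23 to 0.76).

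Large genes at common fragile sites, where low-dose aphidicolin delays replication, were lower as a group in the APH library. The median log2 ratio of 40 measured members was -0.27 (interval -0.45 to -0.05), lower than in all 10000 random lists matched on level and at the 0.26 percentile of lists matched on level and span. FAM172A was lowest at -0.93 (-1.15 to -0.72). LPP, which encodes a focal adhesion protein (ENSG00000145012, hg19 chromosome 3, 187871072 to 188608460), had 2283 counts against 3036 and a ratio of -0.57 (-0.65 to -0.49). The phosphatase gene PTPRG had the same ratio of -0.57 (-0.66 to -0.47), and VPS13B, a lipid transfer protein gene, -0.59 (-0.68 to -0.50). NEGR1, a neural adhesion gene, and MAD1L1, a spindle checkpoint gene, stood at -0.03 (-0.12 to 0.06) and -0.04 (-0.13 to 0.06). Of the 40 members, 5 were at least 1.5-fold lower, 1 was higher and 34 were neither. With total counts, which add 0.0983 to every log2 ratio, the group's median was -0.17 (-0.35 to 0.05), an interval that includes 0. The group's place among random lists does not depend on that factor. The higher member, IL1RAPL1, rested on 108 counts against 63 (0.61, 0.15 to 1.09). The random lists matched on span held all genes of at least 500 kb in a single class. In that class, the 28 genes from 1000 kb had a median of -0.26 (-0.36 to 0.04). The percentile of those lists thus does not separate fragile sites from length among the longest genes.

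Long genes in general stood slightly lower in the APH library. The 516 genes of at least 300 kb had a median log2 ratio of -0.12 and the 5809 genes under 30 kb one of 0.03. The difference was -0.15 (interval -0.20 to -0.12), and 10000 random pairs of sets matched on level ranged from -0.01 to 0.08. Random sets were drawn from genes outside the class they stood for wherever enough remained, so their range leans above 0 and is not a neutral reference. At least 1.5-fold lower were 33 of the long genes (6.40%), against 1.58% of all genes, and 15 (2.91%) were higher, against 3.27% of all. Lower genes were not confined to long ones. The 569 genes under 3 kb, histone genes among them, had a median of -0.06 (-0.09 to -0.03), with 54 lower and 15 higher. With long genes taken from 100 kb, the difference was -0.09. Factors that act on transcription elongation and R-loops had a median of -0.07 over 24 members, inside the range of random lists, and total counts turned it to 0.03. In that list the elongation factor SUPT5H stood at 0.15 and the helicase DDX5 at -0.07, which turned to 0.03 with total counts.

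**Figure D2:**
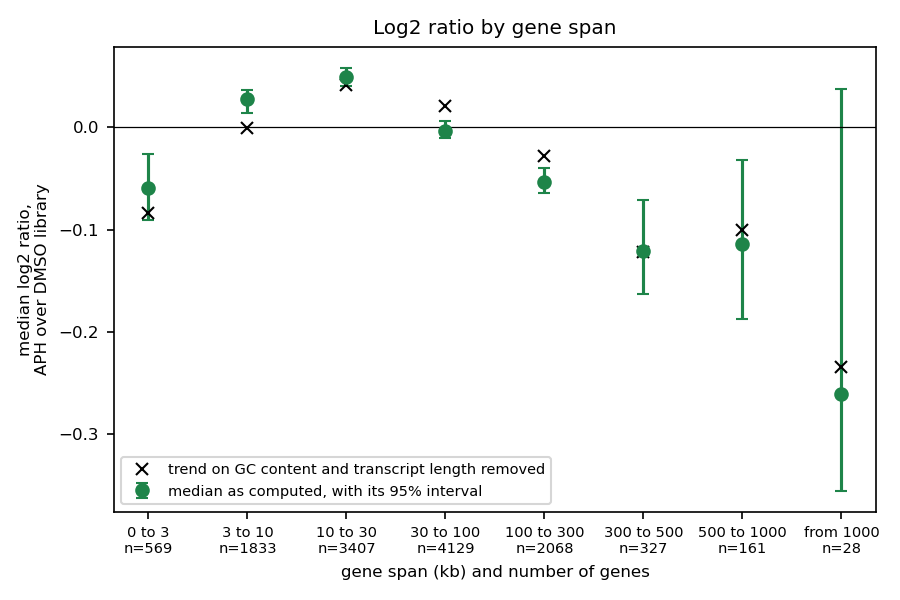
Median log2 ratio of the APH over the DMSO library (vertical axis) in 8 classes of gene span in kb (horizontal axis, with the number of genes), as circles with 95% intervals, and as crosses after a trend on GC content and transcript length was removed. Medians lie at 0.05 for 10 to 30 kb and at -0.12 for 300 to 500 kb, and the interval of the 28 genes from 1000 kb includes 0.

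Genes of DNA replication and the cell cycle differed little. Genes transcribed at the G1/S transition had a median log2 ratio of -0.10 (interval -0.15 to -0.04) over 37 members, at the 2.85 percentile of random lists, and it came to -0.00 when libraries were scaled by total counts. POLA1, the catalytic subunit of polymerase alpha, was the only member at least 1.5-fold lower, with 948 counts against 1378 (-0.70, -0.82 to -0.58). With a span of 303 kb, POLA1 is also among the long genes described above. The helicase subunit genes MCM5 and MCM6 stood at -0.45 and -0.42, while CCNE2, a cyclin E gene, was highest at 0.38 (0.16 to 0.61) and RRM2, a ribonucleotide reductase gene, reached 0.32 (0.28 to 0.36). Replicative polymerases and primase had a median of -0.12 (-0.44 to -0.04) over 12 members, at the 2.94 percentile. Besides POLA1, they included PRIM2 at -0.48, which may share reads with near-identical copies, POLD2 at -0.10 and POLA2 at 0.18 (0.08 to 0.28). Genes of G2 and mitosis had a median of 0.08 (0.01 to 0.13) over 40 members, at the 99.98 percentile, and none passed 1.5-fold. It came to 0.03 (-0.05 to 0.08) with upper quartiles. The ubiquitin-conjugating enzyme gene UBE2C stood at 0.54 (0.47 to 0.62), the topoisomerase gene TOP2A at 0.33 (0.29 to 0.36) and the proliferation marker MKI67 at -0.31 (-0.34 to -0.27).

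Repair and checkpoint genes, which act at stalled forks, had list medians inside the range of random lists. Fanconi anaemia genes had a median log2 ratio of -0.05 over 23 members (13.6 percentile), with FANCF lowest at -0.60 (-0.96 to -0.25), FANCL highest at 0.23 and the deubiquitinase gene USP1 at -0.16. Homologous recombination genes had one of -0.06 over 26 members (8.06 percentile), from RMI1 at -0.52 (-0.77 to -0.27) to RAD51D at 0.36 (0.05 to 0.68), with NBN at -0.08. Genes of the ATR checkpoint had -0.00 over 22 members (60.3 percentile), with TIPIN, a fork protection factor, at -0.41, TP53BP1 at 0.14 and TOPBP1 at -0.03. Translesion polymerases had -0.04 over 13 members (23.8 percentile), with REV3L at -0.39, POLB at 0.29 and MAD2L2 at 0.20. Scaling by total counts turned these 4 medians positive, median ratios turned that of the ATR genes to 0.03 and a count minimum of 500 to 0.02, and NBN came to 0.02. Targets of p53 had a median of 0.04 (0.01 to 0.16) over 33 members (89.2 percentile), which upper quartiles turned to -0.01. GDF15, a stress-induced cytokine gene, was the only target at least 1.5-fold higher, with 312 counts against 122 (1.19, 0.89 to 1.51). The cell cycle inhibitor CDKN1A, the most counted target, stood at 0.30 (0.24 to 0.35) and TRIAP1 at -0.24.

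Interferon-stimulated genes, which restrict viruses and answer cytosolic nucleic acids, were higher as a group. The median log2 ratio of 23 measured members was 0.28 (interval 0.22 to 0.58), higher than in all 10000 random lists. The 6 members at least 1.5-fold higher were OAS1, BST2 at 1.35 (0.71 to 2.07), IFI44 at 0.77, IFIT2 at 0.74, SAMD9L at 0.68 (0.44 to 0.93) and IFIT3 at 0.63 (0.28 to 0.99), and none was lower. LGALS3BP, the most counted member, stood at 0.25 (0.18 to 0.31), and DDX60 was lowest at -0.03 (-0.35 to 0.29). OAS1 and BST2 had under 100 counts in each library. Targets of NF-kB had a median of -0.01 over 15 members (34.9 percentile), which turned to 0.08 with total counts, 0.02 with median ratios and 0.20 (-0.14 to 0.85) with a count minimum of 20. They ran from PTGS2, the only member past 1.5-fold, to ZC3H12A at -0.47 (-0.83 to -0.12), with SOD2 at -0.03.

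Genes of cholesterol synthesis and uptake had a median log2 ratio of 0.19 (interval 0.16 to 0.30) over 25 members, higher than in all random lists. CYP51A1, a demethylase gene of the pathway, was highest at 0.54 (0.22 to 0.86) and TM7SF2 was the only member past 1.5-fold, at -0.73 (-1.21 to -0.27). Genes of the unfolded protein and ATF4 responses had a median of 0.16 (0.10 to 0.20) over 28 members, also above all random lists, with none past 1.5-fold. NUPR1 stood at 0.51 (0.37 to 0.65), ATF3 at -0.35 (-0.55 to -0.15) and the chaperone gene HSP90B1 at -0.07, which turned to 0.03 with total counts. Heat shock genes had a median of -0.08 over 18 members (28.3 percentile) and immediate early genes -0.09 over 25 (3.43 percentile), and total counts turned both positive. CHORDC1 was lowest among heat shock genes at -0.58, BAG3 highest at 0.26, and HSP90AB1 stood at -0.22. EGR1, a growth factor response gene, was the only immediate early gene past 1.5-fold, at -0.75 (-1.01 to -0.50), against SPRY2 at 0.47 and CTGF at 0.27 (0.21 to 0.32).

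Matrix genes were higher as a group, with a median log2 ratio of 0.20 (interval 0.07 to 0.34) over 28 members, above all random lists. LOX, the laminin gene LAMB1 at 0.61 (0.54 to 0.68) and the collagen gene COL11A1 at 0.59 (0.49 to 0.69) were at least 1.5-fold higher. The most counted, the basement membrane collagen gene COL4A2, stood at 0.15 (0.12 to 0.18). Osteoblast markers had a median of 0.44 (-0.35 to 0.77) over 8 members, at the 99.91 percentile. The median came to 0.04 with a count minimum of 500, which left too few members for an interval. SPP1, the osteopontin gene, stood at 0.77 (0.42 to 1.12), while RUNX2, the master factor of osteoblasts, stood at -0.35 (-0.59 to -0.11). SPARC, a matrix protein gene, stood at 0.04 and turned to -0.01 with upper quartiles. Epithelial markers had a median of 0.30 over 5 members, at the 97.0 percentile, and 0.55 with a count minimum of 20, with the keratin gene KRT8 at 0.30 (0.26 to 0.34), the cadherin gene CDH1 at 0.77 (0.26 to 1.31) and CLDN4 at 0.09. Of 18 breast tissue markers with at least 10 counts, from a list written after the data were examined that also holds KRT8 and SPDEF, 5 were at least 4-fold higher.

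Metabolic, ribosomal and reference genes stayed inside the range of random lists. Glycolysis genes had a median log2 ratio of 0.00 over 22 members, or -0.05 with upper quartiles, and a summed ratio of -0.07. The lactate exporter gene SLC16A3 was at least 1.5-fold higher at 0.89 (0.62 to 1.18), against ENO1 at -0.15 and LDHA at -0.18. Nuclear genes of the respiratory chain had a median of -0.01 over 41 members, from NDUFS4 at -0.38 to NDUFA2 at 0.13, with ATP5B at -0.07. Mitochondrial genes had a median of -0.05 and a summed ratio of 0.26 (0.23 to 0.29) over 12 members, from MT-ND2 at -0.51 to MT-ND3 at 0.56, with MT-CO1 at 0.15. Ribosomal protein genes had -0.11 (-0.14 to -0.09) over 53 members, with RPL4 at -0.20, RPL5 at -0.25 and RPS28 at 0.04. Housekeeping genes had -0.09 (-0.15 to -0.02) over 20 members, with EEF1A1 at -0.19, IPO8 at -0.38 and GUSB at 0.20. Scaling by total counts turned the respiratory, mitochondrial and housekeeping medians positive, median ratios the respiratory one, and ATP5B came to 0.03. Neural markers had a median of 0.06 and a summed ratio of -0.03 over 7 members, between NEFL at -0.19 and SNAP25 at 0.38. A count minimum of 500 left only NEFL of the neural markers, at -0.19, and turned the mitochondrial median to 0.05. Of the blood cell markers only CORO1A (0.30) and LCP1 (0.54, 0.14 to 0.96) were measured, with a median of 0.42 at the 90.5 percentile.

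**Figure D3:**
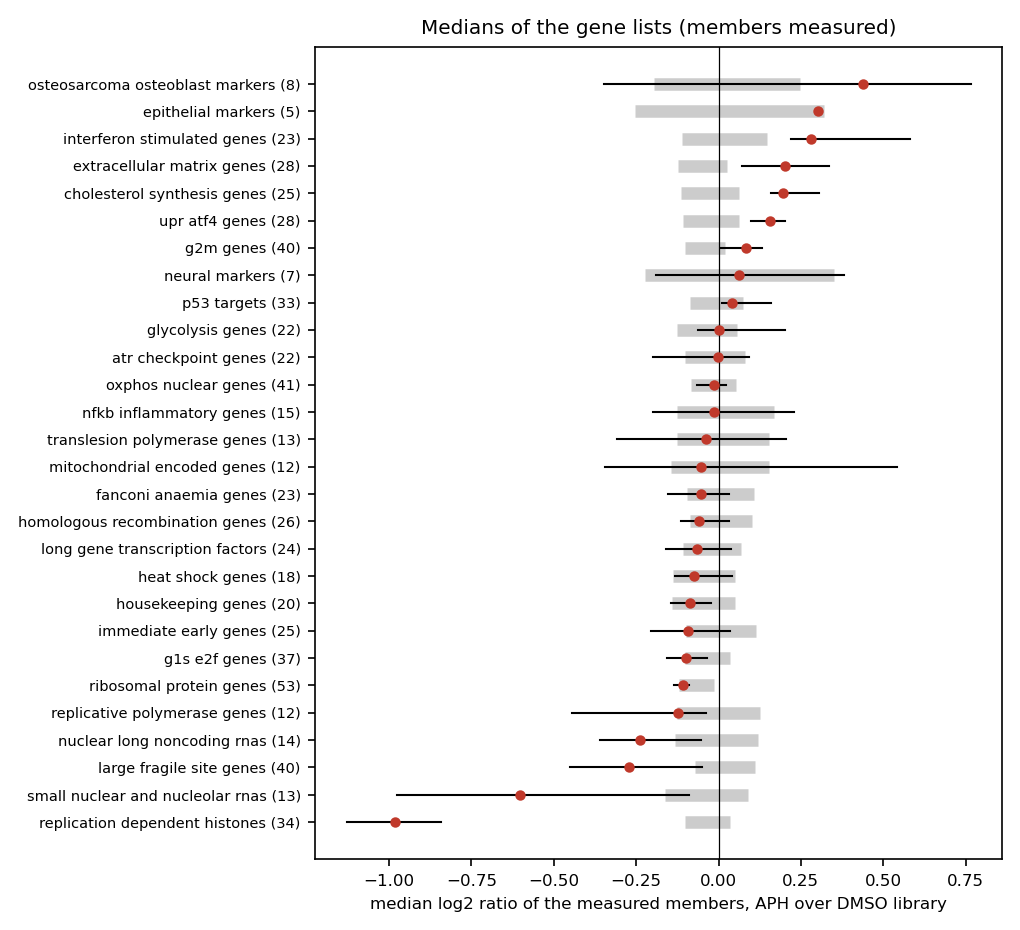
Median log2 ratio of the APH over the DMSO library (horizontal axis) for each gene list fixed before the data were examined and with at least 5 measured members (vertical axis, number in parentheses), as points with 95% intervals where the list has enough members, over grey bars for the central 95% of 10000 random lists. Histone genes lie lowest at -0.98, and interferon-stimulated genes at 0.28 lie above their grey bar.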

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

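No test was chosen for this part. For 14 genes the table gives a count in 1 library and a missing value in the other, and none of them entered a comparison. The DMSO value was missing for LIFR, LARP6 and LAMP2, and the APH value for BTF3, FRYL, GART, PTAR1, ERLEC1, CCDC80, MRAS, PCID2, TAF11, GPN1 and PKN3. The count that was given ran from 744 for PKN3 to 7048 for BTF3, above the floor of 3 counts. It does not show what the other library held, so the missing values were not treated as 0. Why they are missing was not tested.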

How the results depend on the processing

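The settings without liver marker, replication-dependent histone or small RNA genes, with the trend on GC content and transcript length removed, and with a count minimum of 1000 for matrix genes were chosen after seeing the data, and all others before. No paired analysis was possible because each condition had 1 library. Under scaling by total counts, which adds 0.0983 to each log2 ratio, 668 genes were higher and 123 lower. The list medians became -0.000644 for G1/S genes, 0.18 for G2 and mitosis genes, 0.045 for Fanconi anaemia, 0.039 for homologous recombination, 0.095 for the ATR checkpoint, -0.024 for replicative polymerases, 0.26 for the unfolded protein response, 0.086 for the respiratory chain, -0.0096 for ribosomal proteins and 0.012 for housekeeping genes. Median ratios gave 0.024 for the respiratory chain and -0.071 for ribosomal proteins. Upper quartiles gave -0.014 for p53 targets, 0.14 for cholesterol genes, -0.067 for the respiratory chain and -0.16 for ribosomal proteins. These moves follow from the single factor each scaling applies. With no count minimum, 767 genes were higher and 628 lower. A minimum of 500 gave 130 and 77, and a 2-fold threshold 68 and 46, as stricter limits leave fewer genes. The difference between long and short genes was -0.20 with a minimum of 500 and -0.093 with long genes from 100 kb, and the cause was not tested. Of single genes whose interval excluded 0, SPARC reversed to -0.011 under upper quartiles, and NBN at 0.015, ATP5B at 0.0331, HSP90B1 at 0.0328 and DDX5 at 0.029 reversed under total counts. The epithelial median became 0.55 with a minimum of 20, as more members entered. The other 178 values of counts, medians and the span difference stayed within 1.5 times the main value (counts, and lists too short for an interval) or inside the main interval. Some of these could not change. A scaling factor cancels in the span difference, random lists matched on span leave the fragile-site median as it is, and some lists lose no member with another count minimum. Of single genes, 371 values stayed inside the interval and 84 moved beyond it, and 4 of the 84 (NEGR1, MAD1L1, TOPBP1 and SOD2, under total counts) changed sign, as did 8 of the 371, from intervals that included 0. The fragile-site median ranged from -0.32 to -0.17 and the histone median from -1.04 to -0.88 over the settings tried. Genes near 100 counts have intervals about as wide as the differences reported for them, as OAS1 shows at 0.78 to 2.04.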

Other observations

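In this part, the tests of liver RNA, RNA without poly(A) tails, G1/S genes and unspliced RNA were chosen only after the result was seen, as was the choice to remove a trend on GC content and transcript length, and single genes and the added lists were picked after their values were seen. Histone genes that are also transcribed outside S phase had a median log2 ratio of -0.13 (interval -0.59 to 0.11) over 10 members. The linker histone genes H1F0 at -1.03 (-1.10 to -0.96) and H1FX at -0.59 (-0.70 to -0.48) were at least 1.5-fold lower. The core variants H2AFZ at -0.14, H3F3B at -0.20, H3F3A at -0.00 and H2AFX at 0.11 (0.02 to 0.19) were not.

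DHRS2, a short-chain reductase gene, had 17613 counts against 29619 (-0.91, -0.94 to -0.88). GTDC1 and DPH6 stood at -1.19 (-1.51 to -0.89) and -1.17 (-1.63 to -0.73). In the other direction, KRT34, a hair keratin gene, had 647 counts against 232 (1.32, 1.10 to 1.54) and FLT1, a VEGF receptor gene, 211 against 74 (1.34, 0.96 to 1.75). Among the adjacent myosin genes, MYH4 had 24 counts against 77, MYH1 22 against 58 and MYH8 40 against 82, while MYH2 had 69 against 81 and MYH13 243 against 221. Of 10 skeletal muscle markers with at least 10 counts, 0 were at least 4-fold lower in the APH library.

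Liver transcripts were found in the DMSO library. Of 63 liver markers with at least 10 counts, 49 (77.8%) were at least 4-fold lower in the APH library, against 0.354% of 18912 other genes, and 23 had 0 counts there. The 49 genes held 4308 counts in the DMSO library, 0.0242% of it, led by ALB with 1819, and 104 in the APH library. Reads from liver RNA may account for them, yet the test also asked that all of the 10 most counted markers be at least 4-fold lower, and 4 were, while SERPINA1 (491 counts against 561), CPS1 (454 against 568), C3 (217 against 284), RBP4 (111 against 142), SAA1 (205 against 109) and TDO2 (66 against 63) were not. Those markers had counts in both libraries, so they cannot decide where the reads of the 49 lower genes came from. Hepatocyte gene expression by the cells themselves stays open, and FOXA2, the only hepatocyte regulator listed with at least 100 summed counts, stood at 0.36 (-0.08 to 0.80).

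For the lower histone transcripts, poorer recovery of short transcripts is argued against, because 230 other protein-coding genes with transcripts under 1 kb had a median of 0.011 (-0.02 to 0.04). For a lower share of cells at the G1/S transition, the G1/S median of -0.10 (-0.15 to -0.04) had an interval above the bound of -0.25 set for it. That argues against a fall of G1/S transcripts as large as that of the histones. It cannot decide on a lower share of cells in S phase, because how closely G1/S transcripts follow that share was not measured. Poorer recovery of RNA without poly(A) tails cannot be told apart from an effect of treatment. RN7SK at -0.090 and RMRP at 0.08 went against it, but they are only 2 members of a class whose median of -0.60 (-0.97 to -0.09) met the bound of -0.5 while its interval did not lie below -0.25 as the test, added after those values were seen, also asked. Lower histone mRNA under slowed DNA synthesis, the biological explanation the design offers, was not tested.

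For the lower long genes, the difference without liver, histone and small RNA genes was -0.16 (-0.20 to -0.12), but 90 genes are too few to move it, so that test decides nothing. Removal of the trend on GC content and transcript length left -0.13 (-0.16 to -0.10). That is 88.6% of the difference, above the bound of 66.7% written before this test was run. The end of the interval nearest 0 is 66.1% of the unadjusted difference. That share takes the unadjusted difference as fixed, though both values come from the same genes. Most of the difference thus stayed, and a smaller part played by that bias stays open. More reads from unspliced RNA in the DMSO library may contribute. Nuclear long non-coding RNAs had a median of -0.24 (-0.36 to -0.05), below the difference of -0.15, so the test was met. The test set a median, which depends on the scaling, against a difference, which does not. With total counts the median was -0.14 (-0.26 to 0.05), just short of the difference. Scaling shifts all genes alike, however. The nuclear RNAs therefore stay below both the long genes (median -0.12) and the short genes (0.03) under every scaling. The explanation stays open, since no value for introns was analysed here. Slower transcription or replication of long genes under aphidicolin stays open as well and was not tested.

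A few genes with low counts were higher in the APH library, among them CPB1 (41 counts against 1), SFRP2 (15 against 1), IGHA1 (26 against 3), CLEC3A (23 against 4) and IGHG1 (13 against 2). Of 18 breast tissue markers with at least 10 counts, these 5 (27.8%) were at least 4-fold higher, between the bounds of 10% and 50% set for reads from breast tissue RNA, and the list had been written after they were seen. The test therefore left that source undecided. SPDEF, also listed, stood below the 4-fold limit, with 82 counts against 20.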
